A study of Danio rerio with 5 samples.

How the data were processed

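RNA was measured by sequencing in 5 libraries of whole zebrafish (Danio rerio) embryos at 4 hours after fertilisation. The system was RfxCas13d, an RNA-guided nuclease that degrades target transcripts. The 3 control libraries, replicates 1 to 3, came from embryos described as RfxCas13d controls. The other 2 libraries came from embryos described as knockdowns: 1 library with a pool of 10 guides (a guide against szrd1 and 9 others) and 1 library with a pool of 25 guides (the szrd1 guide and 24 others). The targets of the other guides are not given in the sources used here. Per the labels' protocols, libraries were made with the Nextera XT kit at 1/4 of the reaction volume for control replicates 1 and 2, and at 1/8 for control replicate 3 and both pools. The volume is therefore partly confounded with the comparison, since control replicate 3 is the only control made at the volume of the pools. Nothing in the labels says that the controls came from separate clutches or injections, so p-values measure only the spread between these samples, which may be technical.

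The authors deposited gene counts for each library, as whole numbers that sum to different totals, and a second table per gene. The second deposited table was read as TPM, a unit scaled for transcript length and library total, from its values and column sums, since the steps that made it are not given in the sources used here. Reads were converted with bcl2fastq 2.20 and the genome build was danRer11, per the submitters' processing notes. The aligner and the counting program are not given in the sources used here. Genes that share reads with near-identical copies, such as the fthl ferritin genes, core histone genes and cytosolic ribosomal protein genes, are uncertain. The count tables also hold entries that name no gene, such as unmapped or ambiguous reads. These made up 27.1%, 32.0% and 53.8% of the reads in control replicates 1 to 3, 33.9% in the pool of 10 and 26.7% in the pool of 25, and were left out of library sizes and tests. Unmapped reads alone were 44% in control replicate 3 and between 13.1% and 21.0% in the other libraries. Gene symbols were those of the deposited tables, matched by gene identifier. Gene coordinates are not printed.

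Normalised read counts (CPM), which are counts scaled to a common library total, were computed from the deposited gene counts with TMM scaling in edgeR 4.0.16 (R 4.3.3, limma 3.58.1). Of 32520 genes, 16445 passed edgeR's expression filter with a minimum count of 10 and were tested. The test was edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values below are from this test unless another tool is named. A single fit over all 5 libraries held 3 groups and left 2 residual degrees of freedom, so that the spread came from the controls and each single pool library was assumed to vary like them. Both pools together were compared with the controls in a fit with 2 groups and 3 residual degrees of freedom. Alternatives were DESeq2 1.42.0, limma voom, other scaling factors, other filters, the deposited TPM with limma (log2 of TPM + 1, or + 0.1), a term for the library volume, and leaving out each control in turn. The groups, tests, gene lists, named-gene rule and these alternatives were chosen before the data were examined. A floor of 20 CPM, the gene lists with each control left out, a different control for each pool, and all alternatives of the 2-fold rule described next, were chosen after seeing the data. The volume term left 1 residual degree of freedom in the 3-group fit and 2 in the 2-group fit. It takes up the level of control replicates 1 and 2, so fold changes with it set the pools against control replicate 3 alone. The spread is then that between control replicates 1 and 2 and, in the 2-group fit, also between the pools.

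The genes named were szrd1 and, for each comparison, those past the threshold. The rule also stated that, where fewer than 5 genes passed, the 10 lowest and 5 highest genes by fitted fold change were to be named by size with no p-value, among genes at least 2-fold outside the range of all 3 controls with a mean of at least 10 CPM. After values were seen the size rule was tightened, so that a gene at 0 in every library compared cannot pass. For each list, the members with the smallest unadjusted p were named. Further genes in the comparison of both pools, marked as such below, were chosen after their values were seen. In the comparison between pools, the 2-fold distance from the controls was required of either pool. The counts of genes by the 2-fold rule used a stricter floor of 10 CPM than the naming. For a lower gene, every library it was set against had to reach it. For a higher gene, every library in which it was higher had to reach it.

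The 14 gene lists were maternal mRNAs cleared after genome activation, maternal transcription factors of genome activation, zygotic genes induced by this stage, enveloping layer markers, yolk syncytial layer markers, germ plasm and germ cell mRNAs, p53 response, interferon response, integrated stress response, heat shock proteins, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, RNA decay and deadenylation, and replication-type cell cycle genes. Of 361 list entries, 277 were matched by symbol, 80 by a name pattern and 4 were unmatched. Lists were tested with camera (preset inter-gene correlation 0.01), with camera using an estimated correlation, and with fry. Adjustment was over the 14 lists within each comparison.

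Relative transcript length was estimated for each gene from the deposited count over the deposited TPM, and the 2-fold rule was repeated after removal of a trend of each library's deviations with that length. Shared-control effects were estimated from 100 simulations. In these, all libraries were drawn around the mean of the controls with the spread of the 3-group fit, and both unchanged pools were set against the same simulated controls. The simulated controls hold no library volume difference. The test was checked on simulated counts for the comparison of the pool of 25 with the controls, with 200 genes lowered, 100 of them 4-fold and 100 of them 8-fold. With the spread of the 3 controls, 0% of the 4-fold and 0% of the 8-fold changes were called among 15746 genes. With the spread left after the volume term, but in the same 3-group fit without that term, 88% and 100% were called among 15763 genes, with 9 false calls. With closely matched libraries, 100% and 100% were called among 15416 genes, with 8 false calls. The lowered genes were drawn only from genes with mean levels well above 10 CPM, and the simulated counts held no volume difference. These shares therefore do not give the power of the fit with the volume term, nor that for genes at lower levels. Total gene counts ranged from 5283761 to 14179837. A count of 3 in a library, used as the detection floor, was worth 0.255, 0.252 and 0.519 CPM after TMM scaling in control replicates 1 to 3, 0.405 CPM in the pool of 10 and 0.411 CPM in the pool of 25. Intervals and floors based on counts cover counting error only. The biological coefficient of variation was 55.1% in the 3-group fit and 38.6% with the volume term.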

Results

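Transcriptomes of whole zebrafish embryos were compared at 4 hours after fertilisation, close to the time at which the embryo's own genome is activated and maternal transcripts are being cleared. They were controls for the RNA-targeting nuclease RfxCas13d (3 libraries) or knockdowns with RfxCas13d and pooled guides (1 library with 10 guides and 1 library with 25 guides). The question was how many guides can be co-injected when searching for efficient ones, and szrd1 was the target named for both pools. Gene counts totalled 13104114, 14179837 and 5283761 in control replicates 1 to 3, 6872714 in the pool of 10 and 6528043 in the pool of 25. In the same order, 20339, 21052, 17939, 18398 and 18683 genes had at least 1 count. Each pool had no replicate. Across genes, Pearson's r of log2 CPM was 0.955 between control replicates 1 and 2, and 0.892 and 0.887 between each of these and control replicate 3. It was 0.941 and 0.945 between control replicate 3 and the pools of 10 and 25, and 0.966 between the pools. Genes are not independent replicates, and control replicate 3 shared the library volume of the pools.

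The targeted transcript, szrd1 (ENSDARG00000056338), was low in both pools. Its level was 221, 278 and 311 CPM in control replicates 1 to 3, with a mean of 270 ± 45.6 CPM (SD, n = 3). It was 41.3 CPM in the pool of 10, or 15.3% of the control mean, and 45.6 CPM in the pool of 25, or 16.9%. The deposited TPM gave 169.5 ± 72.9 (SD, n = 3) in the controls, 33.4 in the pool of 10 and 42.9 in the pool of 25. The log2 fold change was -2.71 (SE 0.704, 95% interval -4.26 to -1.15) in the pool of 10 and -2.57 (SE 0.698, interval -4.11 to -1.02) in the pool of 25. Neither passed edgeR's test after adjustment over all genes (adjusted p = 0.951 and 0.913; unadjusted p = 0.00292 and 0.00386). DESeq2 called both (adjusted p = 0.013 and 0.041). With both pools against the controls the log2 fold change was -2.63 (SE 0.397, unadjusted p = 5.58e-05, adjusted p = 0.232). With a term for library volume it was -2.84 (SE 0.273, interval -3.45 to -2.23, adjusted p = 0.0209), the smallest p of the 16445 genes. The volume term takes up control replicates 1 and 2, so this value sets the pools against control replicate 3 alone. Without control replicate 3 the log2 fold change was -2.53, with an adjusted p of 0.00168. The controls left were then all of the other library volume, and 1001 genes lay at least 2-fold below and 1036 above them in both pools. Over all alternatives run, the adjusted p ranged from 0.013 to 1 for the pool of 10, from 0.041 to 1 for the pool of 25 and from 4.6e-08 to 0.608 for both pools together, always with a negative log2 fold change.

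The level of szrd1 in the pool of 25 differed from that in the pool of 10 by a log2 fold change of 0.14 (SE 0.726, 95% interval -1.46 to 1.75, unadjusted p = 0.85). The interval allows ratios from 0.362 to 3.35, or from 0.596 to 2.04 with the volume term, so a loss or gain of activity within these limits is not excluded.

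**Figure D1:**
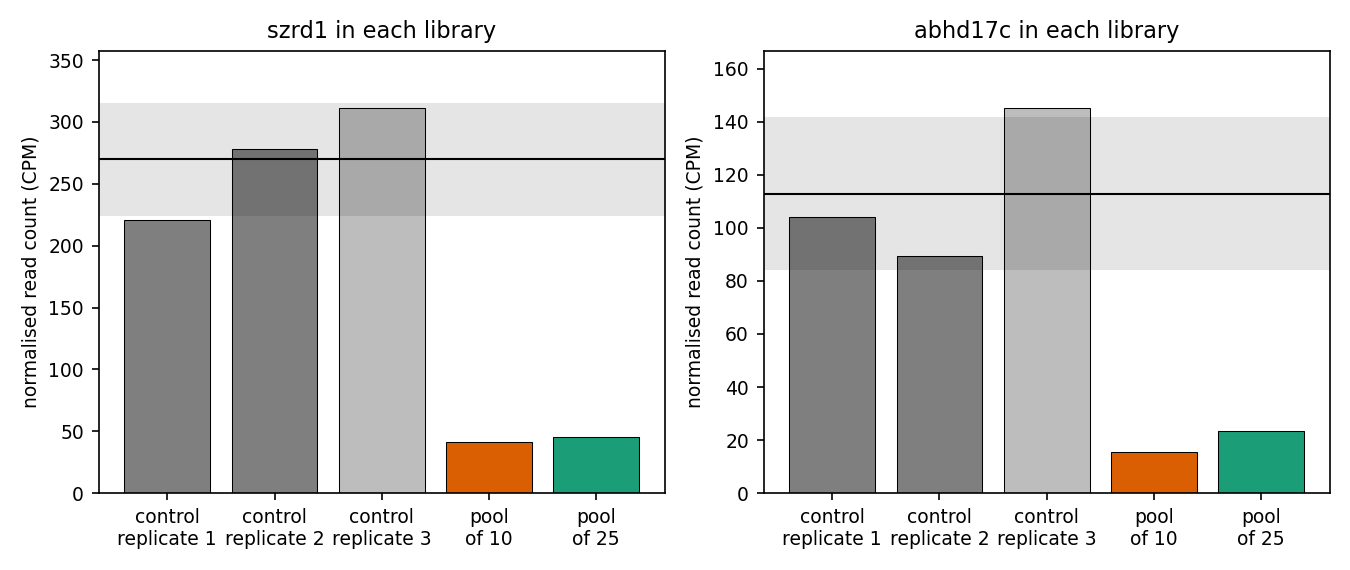
Normalised read count (CPM, y axis) of szrd1 and abhd17c in each of the 5 libraries (bars, x axis), with the mean of the 3 controls (line) and 1 SD on each side (shaded). szrd1 lay at 41.3 and 45.6 CPM in the pools of 10 and 25 and above 220 CPM in all controls; abhd17c lay at 15.4 and 23.4 CPM in the pools and above 89 CPM in all controls.

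In the pool of 10, transcripts of several genes seen at low levels in the controls were at or near the detection floor. The melanosome transport gene mlpha had 11.9 ± 2.89 CPM in the controls (SD, n = 3) and no count in the pool, at least 29.3-fold lower. The connexin gene cx35.4 had 10.4 ± 2.42 CPM and no count (at least 25.8-fold lower). Also without a count in the pool were the acetylcholine receptor subunit gene chrnb3a, at 11.5 ± 10.9 CPM (at least 28.3-fold lower), and si:dkey-23i12.9, at 18.9 ± 12.1 CPM (at least 46.7-fold lower). Single controls carried much of these 2 bounds, which were 14.5-fold for chrnb3a without control replicate 3 and 29.5-fold for si:dkey-23i12.9 without control replicate 2. There was no count in the pool either for si:ch211-254n4.3, at 13.5 ± 10.7 CPM (at least 33.3-fold lower), and CU466278.1, at 11.4 ± 5.59 CPM (at least 28-fold lower). For si:ch211-254n4.3, control replicates 1 and 2 were at 19.9 and 19.4 CPM and control replicate 3 at 1.21 CPM. The ferritin-like gene fthl28 had 98.8 ± 53.6 CPM in the controls and 1.62 CPM in the pool (log2 fold change -5.92, SE 1.14, and -4.56 with the volume term). It belongs to a family of near-identical copies and its counts are uncertain.

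Other low genes in the pool of 10 had 1 to 3 counts. The ratio to the control mean, with its counting interval, was 0.0117 (2.95e-04 to 0.065) for the calpain gene capn12. It was 0.0121 (3.07e-04 to 0.0676) for the transcription factor gene hnf4b and 0.0382 (0.00787 to 0.112) for the ceramide synthase gene cers2b. For hnf4b, control replicates 1 and 2 were at 1.02 and 0.336 CPM and control replicate 3 at 32 CPM, and for capn12 the controls were at 2.13, 5.97 and 26.7 CPM. Without control replicate 3 the ratio was 0.199 (0.00504 to 1.11) for hnf4b and 0.0334 (8.45e-04 to 0.186) for capn12. The highest genes included sned1 (0.141 ± 0.177 CPM in the controls and 18 CPM in the pool) and the myosin-binding protein gene mybpc2b (0.626 ± 0.325 and 18.5 CPM). They also included ankrd33bb (1.45 CPM in control replicate 1, no count in the other controls and 11.9 CPM) and CABZ01075125.1 (1.93 ± 0.907 and 36.7 CPM). A gene with a provisional symbol was at 1.11 ± 0.673 and 13.1 CPM.

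These genes were named by size, since edgeR called 0 genes lower and 0 genes higher in the pool of 10 (smallest adjusted p = 0.636). At an unadjusted p under 0.05 there were 296 lower and 234 higher. DESeq2 called 6 lower and 3 higher. By size alone and with the stricter 10 CPM floor, 93 genes lay at least 2-fold below and 174 at least 2-fold above every control. Without control replicate 3 these counts were 1273 and 1399. Genes with a control under 10 CPM, such as mlpha and hnf4b named above, are not among the 93. Set against the other 2 controls, control replicate 3 itself had 1484 genes lower and 1531 higher by the same rule. Control replicate 1 had 208 and 189, and control replicate 2 had 103 and 312. With library size as the only scaling, 67 genes lay below and 235 above.

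Transcripts of cytosolic ribosomal proteins were lower as a group in the pool of 10, with 78 of 79 measured members below 0 and a median log2 fold change of -1.05 (camera, adjusted p = 1.08e-11). This call was lost with an estimated correlation (adjusted p = 0.815 with an estimated correlation). rpl18 was at 223 ± 112 CPM in the controls and 74.1 CPM in the pool, and rps13 at 55.1 ± 25.4 and 19.2 CPM. In control replicate 3 against control replicates 1 and 2, the median of the same list was -1.46, with 79 of 79 members below 0. Against the same 2 controls the pool was at -1.40, and with the volume term it was at 0.07. Values of control replicate 3 given below for other lists are also against control replicates 1 and 2. They thus have another baseline than the pool medians. RNA decay and deadenylation genes were higher, with 26 of 31 above 0 and a median of 0.50 (camera, adjusted p = 0.00342; adjusted p = 0.815 with an estimated correlation), against 0.84 in control replicate 3. With the volume term the median was 0.06 and the call was lost (adjusted p = 0.728), while without control replicates 1 and 3 in turn the medians were 0.32 and 0.84. Their leading members were the decapping genes edc3 (37.1 ± 14.6 and 78.1 CPM) and dcp2 (22.4 ± 2.57 and 44.4 CPM). Germ plasm and germ cell mRNAs had a median of 0.58, with 10 of 15 above 0 (camera, adjusted p = 0.0462, or 0.815 with an estimated correlation). This call was lost with the volume term (median 0.22, adjusted p = 0.345) and without control replicate 2 (0.29, adjusted p = 0.211), and the medians were 0.34 and 0.95 without control replicates 1 and 3. Against control replicates 1 and 2, the germ plasm list was at 0.57 in control replicate 3 and 0.95 in the pool. Its median log2 deviation from the mean over the 5 libraries was -0.17, -0.57 and -0.17 in control replicates 1 to 3. In the pool it was 0.48. The leading member was the germ granule gene tdrd6, at 16.1 ± 5.29 CPM in the controls and 77.5 CPM in the pool (log2 fold change 2.27, SE 0.607), followed by buc, which organises the germ plasm, at 542 ± 141 and 1040 CPM.

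The remaining lists did not pass in the pool of 10. Without control replicate 1, camera at the preset correlation called zygotic genes (median -0.56), enveloping layer markers (-0.98), yolk syncytial layer markers (-1.09) and the p53 response (-0.53) lower. Without control replicate 3 it called maternal mRNAs (-0.55) and mitochondrial mRNAs (-0.74) lower. Fitted with the volume term, mitochondrial mRNAs were called higher instead (0.58, 13 of 13 above 0, adjusted p = 0.000314; adjusted p = 0.89 with an estimated correlation), and maternal mRNAs were at 0.15. That fit sets the pool against control replicate 3 alone. In this library the mitochondrial list was itself low against control replicates 1 and 2 (median -1.11, 12 of 13 below 0). With all controls, zygotic genes had a median of -0.40 (30 of 40 below 0). They included the signalling gene bmp4 at 4.47 ± 2.34 and 0.54 CPM and the pluripotency and neural crest factor foxd3 at 15.1 ± 5.3 and 4.86 CPM. Maternal mRNAs cleared after genome activation had a median of -0.28. They included gtf3ab at 750 ± 367 and 148 CPM and cldnd at 1900 ± 853 and 844 CPM. The maternal transcription factors of genome activation had a median of 0.09, with sox19b at 264 ± 34.6 and 534 CPM and taf15 at 132 ± 69.7 and 65.5 CPM. Medians were -0.68 for enveloping layer markers and -0.83 for yolk syncytial layer markers, with krt5 at 23.2 ± 21 CPM in the controls and 1.89 CPM in the pool and afp4 at 15 ± 18.5 and 1.76 CPM. Medians were -0.35 for the p53 response, -0.83 for the interferon response, -0.27 for the integrated stress response, -0.02 for heat shock proteins, -0.43 for mitochondrial mRNAs and -0.08 for cell cycle genes. Adjusted over the list alone, 0 genes of the 14 lists passed in this comparison.

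In the pool of 25, the lowest transcripts by size were again of genes with low or moderate levels in the controls. ndufs8b, which encodes a subunit of mitochondrial complex I, had 31.1 ± 19.5 CPM in the controls (SD, n = 3) and no count in the pool (at least 75.9-fold lower), and si:dkey-102m7.3 had 16.9 ± 10 CPM and no count (at least 41.1-fold lower). fthl28 was at 4.93 CPM (log2 fold change -4.32, SE 1.02, and -2.96 with the volume term). si:dkey-9c18.3 was at 159 ± 117 and 10.4 CPM (-3.94, SE 1.11, and -2.16 with the volume term), and the tachykinin gene tac3b was at 13 ± 15 and 0.821 CPM. si:dkey-23i12.9 was at 1.09 CPM and BX927081.3 at 11.9 ± 7.86 and 0.547 CPM. Without control replicate 2 the control means were 98.7 CPM for si:dkey-9c18.3, 4.53 CPM for tac3b, 11.9 CPM for si:dkey-23i12.9 and 7.33 CPM for BX927081.3. The ratio to the control mean, with its counting interval, was 0.0105 (2.66e-04 to 0.0584) for the tetraspanin gene tspan4b, 0.0111 (2.8e-04 to 0.0616) for BX001030.2 and 0.0166 (0.00201 to 0.06) for the transglutaminase gene tgm2l. Without control replicate 2 it was 0.0198 (5e-04 to 0.11) for tspan4b and 0.0265 (0.00321 to 0.0958) for tgm2l.

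The highest genes in the pool of 25 were mybpc2b at 19.7 CPM, the myosin light chain kinase gene mylka (0.311 ± 0.402 CPM in the controls and 10.1 CPM), ankrd33bb at 12.5 CPM and a gene with a provisional symbol (0.452 ± 0.469 and 11.6 CPM). CABZ01075125.1 was at 33.7 CPM (log2 fold change 4.10, SE 0.681). edgeR called 0 genes lower and 0 higher (smallest adjusted p = 0.838), with 302 lower and 200 higher at an unadjusted p under 0.05. DESeq2 called 7 lower and 2 higher. By size alone and with the stricter 10 CPM floor, 130 genes lay at least 2-fold below every control and 160 above. Without control replicate 3 these counts were 1456 and 1543. With library size as the only scaling, 86 lay below and 269 above.

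Ribosomal protein transcripts were again lower as a group in the pool of 25 (median -1.30, 78 of 79 below 0, camera adjusted p = 6.12e-16). The call was lost with an estimated correlation (camera, adjusted p = 0.856). The medians against control replicates 1 and 2 alone were -1.46 in control replicate 3 and -1.63 in the pool. Values of control replicate 3 for the other lists have these same 2 controls as baseline. rps15a was at 72.9 ± 38.5 and 19.4 CPM, and 1 of the 2 genes with the symbol rpl37 at 35.3 ± 3.83 and 11.2 CPM. RNA decay genes had a median of 0.47, with 25 of 31 above 0 (camera, adjusted p = 0.00354; adjusted p = 0.856 with an estimated correlation), led by the poly(A) nuclease genes pan2 (43.1 ± 29.7 and 105 CPM) and pan3 (48.9 ± 38 and 120 CPM). Their median was 0.31 without control replicate 1 and 0.87 without control replicate 3. Zygotic genes were lower in this pool, with 33 of 40 below 0 and a median of -0.62 (camera, adjusted p = 0.0166; adjusted p = 0.856 with an estimated correlation), while control replicate 3 had a median of -0.11. The call was lost without control replicate 2 (median -0.29, adjusted p = 0.242) and without control replicate 3 (-0.77, adjusted p = 0.0801). From their mean over the 5 libraries these genes deviated by a median log2 of 0.54 in control replicate 2, -0.17 in control replicate 1, 0.09 in control replicate 3 and -0.30 in the pool. Enveloping layer markers deviated by 1.12, -1.34, 0.56 and -0.15 in the same order. The leading zygotic members were bmp4, at 1 count in the pool (0.137 CPM), and sp5l, with 2.25 ± 1.08 CPM in the controls and no count in the pool. The p53 list had a median of -0.39, with 14 of 17 below 0 (camera, adjusted p = 0.0495; adjusted p = 0.856 with an estimated correlation), beside -0.31 in control replicate 3. Control replicate 2 was above control replicate 1 for 16 of the 17 p53 genes (median log2 difference 0.79). The p53 call was lost without control replicate 2 (-0.19, adjusted p = 0.384) and without control replicate 3 (-0.47, adjusted p = 0.147). With the volume term the camera calls of these 4 lists were lost, at medians of -0.06, 0.05, -0.31 and -0.26.

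Adjusted over the list alone, tdrd6 and gadd45ab passed in the pool of 25. tdrd6 was higher (93.3 CPM, log2 fold change 2.54, SE 0.604, adjusted p = 0.0241 over its list). The DNA damage response gene gadd45ab was lower, at 9.36 ± 4.48 CPM in the controls and 0.137 CPM in the pool (adjusted p = 0.0352 over its list). The germ plasm list as a whole had a median of 0.42, and maternal mRNAs one of -0.47, with cldnd at 703 CPM and gtf3ab at 279 CPM. Without control replicates 1 to 3 in turn, these medians were 0.23, 0.17 and 0.84 for germ plasm and -0.22, -0.40 and -0.64 for maternal mRNAs. Medians were 0.32 for maternal transcription factors (sox19b at 471 CPM), -0.73 for enveloping layer markers, -0.81 for yolk syncytial layer markers and -0.40 for the interferon response. They were -0.33 for the integrated stress response, -0.38 for heat shock proteins, -0.58 for mitochondrial mRNAs and 0.02 for cell cycle genes, and none of these passed. Without control replicate 1, enveloping layer (-1.07) and yolk syncytial layer markers (-1.06) were called lower, and without control replicate 3 maternal (-0.64) and mitochondrial mRNAs (-0.87) were. Control replicate 3 itself was low for the mitochondrial list (median -1.11 against control replicates 1 and 2, 12 of 13 below 0). The volume term sets the pool against this library alone. Mitochondrial mRNAs were instead called higher with the volume term (0.36, 11 of 13 above 0, adjusted p = 0.0476; adjusted p = 0.927 with an estimated correlation), and maternal mRNAs were at 0.03.

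**Figure D2:**
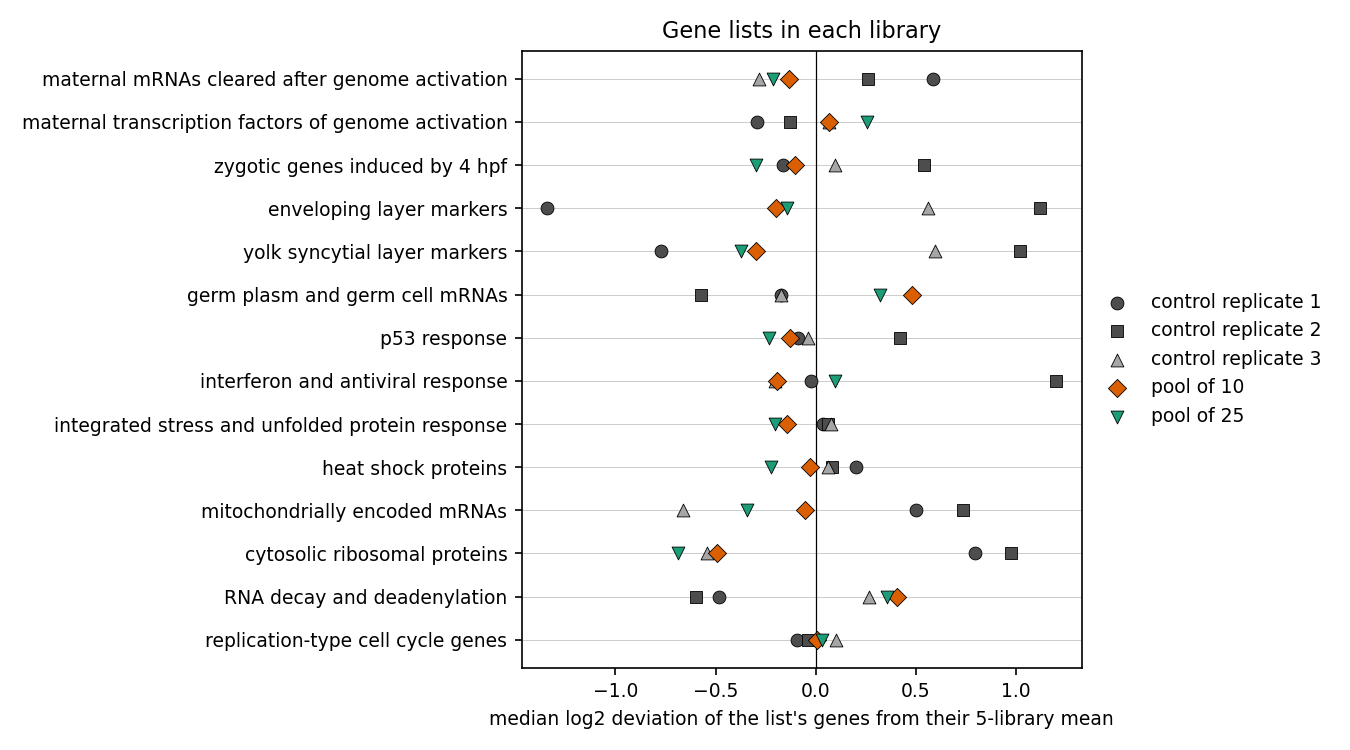
Median log2 deviation (x axis) of the genes of each of the 14 lists (y axis) from their own mean over the 5 libraries, with 1 symbol per library. For ribosomal proteins and RNA decay genes, control replicate 3 lies with both pools and apart from control replicates 1 and 2; enveloping layer markers spread most widely between control replicates 1 and 2.

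The direct comparison of the pool of 25 with the pool of 10 asks whether embryos with more guides differed from those with fewer. The targets of the guides other than that of szrd1 are not given. The number of guides therefore cannot be told apart from which guides each pool held. The poly(A)-binding protein gene pabpn1l was at 353 CPM in the pool of 10 and 74.3 CPM in the pool of 25 (log2 fold change -2.25, SE 0.88, unadjusted p = 0.0274), with 853, 791 and 285 CPM in control replicates 1 to 3. The threonyl-tRNA synthetase gene tars3 was at 15.4 and 1.92 CPM, the protease gene prss23 at 12.2 and 1.78 CPM, and ano10b at 10.5 and 1.64 CPM. rnf165a was at 23.1 and 4.52 CPM and ikbke at 21.9 and 4.93 CPM. These last 5 genes all lay closer to the controls in the pool of 25, as their control means were, in the order named, 1.91, 2.17, 2.51, 8.14 and 5.85 CPM. The transcription cofactor gene eya4 (11 ± 1.44 CPM in the controls) was at 12.2 and 2.46 CPM, the DNA glycosylase gene mpg at 10.1 and 2.05 CPM, TSTD1 at 12.4 and 2.87 CPM and si:dkey-286j15.1 at 10.7 and 2.19 CPM.

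Genes higher in the pool of 25 were efs (1.35 and 12.7 CPM in the pools of 10 and 25), the phosphatase gene phlpp1 (1.89 and 16 CPM) and the Hedgehog pathway gene gli2a (2.16 and 16 CPM). Others were si:ch211-217k17.10 (1.08 and 10.1 CPM) and CU466278.1, with no count in the pool of 10 and 10.1 CPM in the pool of 25. edgeR called 0 genes in either direction (smallest adjusted p = 1), with 55 lower and 75 higher at an unadjusted p under 0.05, and DESeq2 called 0. No list passed, with the largest medians 0.64 for the interferon response (8 of 11 above 0), -0.24 for yolk syncytial layer markers and -0.22 for both zygotic genes and ribosomal proteins. Adjusted over the list alone, 0 genes passed. With 1 library in each group, this comparison has no replicate check of its own and rests on the spread between the controls.

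With both pools joined as the labelled knockdown group and the stricter 10 CPM floor, 37 genes lay at least 2-fold below every control. With the same floor, 73 lay at least 2-fold above every control. szrd1 was among the 37. Some of the others are named here after their values were seen. abhd17c, which encodes a depalmitoylating enzyme, was at 113 ± 28.5 CPM in the controls (SD, n = 3) and at 15.4 CPM (13.7%) and 23.4 CPM (20.8%) in the pools of 10 and 25. FO082779.2 was at 38.5 ± 3.37 CPM and at 9.86 and 9.03 CPM, the phosphatase-like gene ctdspl2a at 54.1 ± 21.3, 18.1 and 16.7 CPM, and nudt12 at 12.2 ± 0.407, 0.81 and 3.7 CPM. The small GTPase gene rap2b was at 47 ± 5.37, 14.6 and 17.7 CPM, the ciliary GTPase gene arl6 at 62.8 ± 2.29, 28.5 and 26.4 CPM, and the stathmin gene stmn1b at 27.3 ± 11.3, 1.08 and 6.84 CPM. Among the 73, the FGF-responsive transcription factor gene etv5a was at 112 ± 9.41 CPM in the controls and 405 and 385 CPM in the pools, the Notch-modifying gene rfng at 38.3 ± 2.5, 172 and 135 CPM, and the clock gene arntl2 at 40.1 ± 3.63, 101 and 117 CPM. The zinc transporter gene slc39a10 was at 20.6 ± 2.79, 97.7 and 64.9 CPM, and the Hedgehog antagonist gene hhip at 3.01 ± 0.112, 30.9 and 15.2 CPM.

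By fitted fold, the lowest genes in both pools together were si:dkey-23i12.9, tspan4b, fthl28 (log2 fold change -4.91, SE 0.762), tgm2l, ndufs8b, cx35.4 and mlpha, with values given before. They also included si:ch211-195b11.3 (12.5 ± 14.7 CPM in the controls, 0.54 and 1.09 CPM in the pools), cfap100 (16 ± 16.7, 1.08 and 1.09 CPM) and CU468915.1 (17.9 ± 12.4, 1.35 and 1.23 CPM). Without control replicate 2 the control means were 4.02 CPM for si:ch211-195b11.3 and 6.62 CPM for cfap100. si:ch211-195b11.3, cfap100 and CU468915.1 were at 3.12, 2.94 and 3.64 CPM in control replicate 3, and their log2 fold changes moved from -3.92, -3.87 and -3.79 to -1.91, -1.42 and -1.48 with the volume term. Those of tspan4b and ndufs8b moved from -4.96 and -4.67 to -3.36 and -2.81. The highest were sned1, mybpc2b (4.95, SE 0.654), ankrd33bb, CABZ01075125.1 (4.16, SE 0.517) and zgc:153738 (1.13 ± 1.09, 13 and 13.3 CPM). edgeR called 0 genes lower and 0 higher (smallest adjusted p = 0.147), with 1096 lower and 653 higher at an unadjusted p under 0.05, and DESeq2 called 67 lower and 39 higher. Without control replicate 3, edgeR called 2180 genes lower and 2030 higher, and 1001 and 1036 genes passed the 2-fold rule.

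With the volume term, edgeR called 3 genes lower in both pools together, namely szrd1, abhd17c (log2 fold change -2.90, SE 0.324, adjusted p = 0.0267) and fthl28 (-3.55, SE 0.477, adjusted p = 0.039). It called 7 genes higher, namely kyat3, slc35a3a, taco1, odf3l2a, pigrl2.3, 1 of the 2 genes with the symbol rrm2, and 1 gene with a provisional symbol. These 7 were also named after their values were seen, and all were lowest in control replicate 3, the only control against which this fit sets the pools. For example, taco1 (1 of 2 genes with that symbol) had 14.1 and 13.7 CPM in control replicates 1 and 2, no count in control replicate 3, and 14.5 and 17.1 CPM in the pools. kyat3 was at 11.2, 10.8 and 1.9 CPM in the controls and at 48.8 and 46.3 CPM in the pools, and slc35a3a at 5.53, 12.2 and 0.346 CPM and at 47.9 and 42.3 CPM.

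In both pools together, ribosomal proteins had a median of -1.12 (78 of 79 below 0, camera adjusted p = 2.77e-18), RNA decay genes one of 0.42 (27 of 31 above 0, adjusted p = 0.000677) and zygotic genes one of -0.45 (32 of 40 below 0, adjusted p = 0.0436). All 3 calls were lost with an estimated correlation (adjusted p = 0.766 with an estimated correlation for each), and with the volume term the medians were -0.04, 0.07 and -0.24. The medians in control replicate 3 against the other 2 controls were -1.46, 0.84 and -0.11. Those of the pools against the same 2 controls were -1.52, 0.87 and -0.53. The zygotic call was also lost without control replicate 2 (-0.20, adjusted p = 0.512) and without control replicate 3 (-0.53, adjusted p = 0.107), and the median of RNA decay genes was 0.87 without control replicate 3. The organiser gene gsc (33.5 ± 12.5 CPM in the controls, 15.7 and 13.7 CPM in the pools) and the ventral factor gene vox (182 ± 89.6, 73.3 and 64.6 CPM) were among the zygotic genes. Adjusted over the list alone, tdrd6 (log2 fold change 2.41, SE 0.424, adjusted p = 0.00292 over its list) and gadd45ab (adjusted p = 0.00588 over its list) passed. The germ plasm list had a median of 0.54, the p53 list one of -0.39 and maternal mRNAs one of -0.37. Without control replicate 1 camera also called the layer markers (-1.02 and -0.97), germ plasm (0.30) and p53 (-0.45) lists, and without control replicate 3 maternal (-0.64) and mitochondrial mRNAs (-0.89). The mitochondrial list had a median of -1.11 in control replicate 3 against the other 2 controls (12 of 13 below 0). The volume term sets the pools against this library alone. With the volume term, the 13 mitochondrial mRNAs had a median of 0.58 (13 of 13 above 0, camera adjusted p = 0.000406; adjusted p = 0.833 with an estimated correlation), whereas without it the median was -0.53, and maternal mRNAs had one of 0.10 with it.

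The overlap of the pools was compared with what the shared controls would give. The 37 genes lower and the 73 genes higher in both pools compare with 1.48 and 2.54 for independent lists (one-sided Fisher's exact test, p = 6.89e-44 and 2.35e-93). They compare with means of 41.7 and 34.2 (highest 57 and 50) in 100 simulations of unchanged pools set against the same simulated controls. The simulated lists held 350 and 359 genes lower and 278 and 279 higher in the pools of 10 and 25. They were longer than the observed ones (93 and 130 lower, 174 and 160 higher), so the shared numbers are no like-for-like measure of chance. Across the 16445 genes, Pearson's r of the log2 fold changes in the pools was 0.741 and Spearman's rho 0.729, against a Pearson's r of 0.249 in the simulations. The covariance was 0.348 against 0.117. Against control replicate 3 alone, r was 0.71, above the simulated 0.503, and the covariance 0.297, below the simulated 0.358. With a different single control for each pool, r was 0.647 and 0.668 where these were control replicates 1 and 2, made at the other library volume. It was 0.0111 to 0.17 in the 4 assignments in which 1 pool was set against control replicate 3. The simulations already hold the sharing of controls, but no library volume difference. With no control shared, r stayed high only where both controls were of the other volume. The excess thus goes with the difference of control replicates 1 and 2 from the other libraries. Any further part from the shared controls cannot be measured, as they cannot be divided into 2 sets of at least 2 libraries.

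**Figure D3:**
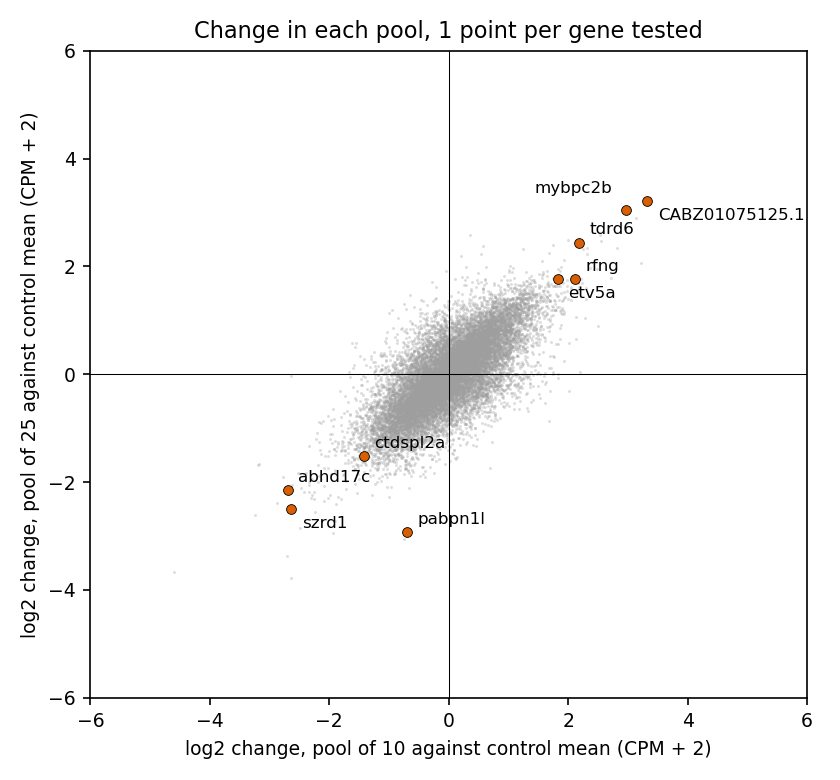
Log2 ratio to the control mean in the pool of 10 (x axis) and the pool of 25 (y axis), computed from CPM + 2, with 1 point for each of the 16445 genes tested and labelled orange points for some of the genes named in the text. szrd1 and abhd17c lie low in both pools, and pabpn1l lies low mainly in the pool of 25 (74.3 CPM against 353 CPM in the pool of 10).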

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

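The floor of 20 CPM, the gene lists with a control left out, a different control for each pool and all alternatives of the 2-fold rule were chosen after seeing the data, and all other alternatives before. No paired analysis was possible because each pool had a single library and shares at most 1 replicate number with the controls. Fits on only the libraries of a comparison were not run for the pool of 25 against the pool of 10, where no spread is left, nor for both pools together. szrd1 kept a negative log2 fold change under every alternative, and the named genes kept their direction under all alternatives in 183 of 191 combinations of gene and comparison. Many of these genes were named for lying at least 2-fold outside the controls in the same data, so this count says little about robustness. Depth limits what can be said of genes near 0.519 CPM, the floor in the shallowest control.

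The log2 fold change of szrd1 gained significance with DESeq2, at -2.72 in the pool of 10, -2.57 in the pool of 25 and -2.64 in both. For both pools it also did without a filter (-2.64) and with the volume term (-2.84), and ranged from -2.76 to -2.53 when a control was left out, with significance only without control replicate 3. The numbers of genes that edgeR called, all 0, became 6 lower and 3 higher in the pool of 10, 7 and 2 in the pool of 25, and 67 and 39 in both with DESeq2, with 2 genes called lower in each pool on its own. Without a filter they were 11 and 8, 5 and 5, and 99 and 38, again with 2 genes called lower in each pool on its own. The volume term gave 3 and 7 in both pools together and 0 in each pool, and TPM of at least 1 gave 1 lower. Leaving out a control gave 0 to 3 lower and 0 to 4 higher in the pool of 10, 0 to 2 and 0 to 3 in the pool of 25, and 0 to 2180 and 0 to 2030 in both. The highest of these last counts came without control replicate 3, which leaves controls of the other library volume alone. The cause of the other differences was not tested.

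With the stricter 10 CPM floor, genes at least 2-fold outside every control numbered 93 lower and 174 higher in the pool of 10. They numbered 130 and 160 in the pool of 25, and 37 and 73 in both, and szrd1 was among the lower in each alternative. A floor of 20 CPM, which tests fewer genes, gave 50 and 109, 75 and 96, and 21 lower in both. A 4-fold limit gave 13 and 17, 8 and 19, and 3 and 8. Library size as the only scaling, which moved the median log2 fold change of all genes in the pool of 25 from -0.13 to 0.12, gave 86 and 269 in the pool of 25 and 23 lower in both. TPM gave 291 higher in the pool of 10, 74 and 336 in the pool of 25 and 133 higher in both. It gave 85 lower in the pool of 10 and 28 lower in both, but many were other genes. Only 30 of the 93 lower genes in the pool of 10 were found again, 39 of the 130 in the pool of 25, and 10 of the 37 in both. Correction for transcript length gave 85 lower in the pool of 25, and 26 lower and 44 higher in both. Control replicate 3 alone gave 491 and 631, 511 and 543, and 227 and 294, since fewer controls have to be passed. Leaving out a control gave 125 to 1273 lower and 216 to 1399 higher in the pool of 10, 157 to 1456 and 198 to 1543 in the pool of 25, and 49 to 1001 and 93 to 1036 in both. The correlation of the pools' log2 fold changes, 0.741, was 0.76 with at least 10 counts in 3 libraries, 0.71 against control replicate 3 only, and 0.679 to 0.844 with a control left out. With a different control for each pool (that of the pool of 10 given first) it was 0.647 for control replicates 1 and 2, 0.668 for 2 and 1, 0.0734 for 1 and 3, 0.17 for 2 and 3, 0.0111 for 3 and 1, and 0.0852 for 3 and 2.

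Of the gene lists, 3 passed in the pool of 10, 4 in the pool of 25 and 3 in both. With an estimated correlation 0 passed in each, with fry 0, and with the volume term 1 in each (mitochondrial mRNAs). With a control left out, 2 to 7 passed in the pool of 10, 2 to 6 in the pool of 25 and 2 to 7 in both, with the fewest without control replicate 2. Medians then changed sign in the pool of 10 for p53 (-0.533 to 0.0943), interferon (-0.923 to 0.215), integrated stress (-0.335 to 0.0536), heat shock (-0.203 to 0.0816) and cell cycle genes (-0.0798 to 0.103). In the pool of 25 they did for enveloping layer markers (-1.07 to 0.0471), heat shock (-0.289 to 0.145) and cell cycle genes (-0.0077 to 0.134), and in both pools for interferon (-0.971 to 0.115) and cell cycle genes (-0.0433 to 0.155). With the volume term, medians changed sign in the pool of 10 for maternal mRNAs (0.151), maternal transcription factors (-0.0887), p53 (0.0437), interferon (0.202), integrated stress (0.173), mitochondrial mRNAs (0.578) and ribosomal proteins (0.0652). In the pool of 25 they did for maternal mRNAs (0.0307), germ plasm (-0.086), interferon (0.727), integrated stress (0.0889), mitochondrial mRNAs (0.356) and cell cycle genes (-0.00355). In both pools they did for maternal mRNAs (0.102), maternal transcription factors (-0.0403), interferon (0.19), integrated stress (0.0829), mitochondrial mRNAs (0.576) and cell cycle genes (-0.0532). Among named genes, log2 fold changes reversed with the volume term for taf15 (0.18), mt-co3 (0.71) and mt-cyb (1.04) in the pool of 10, for mt-nd4l in the pool of 25 (0.14), and for mt-nd4l (0.19), mt-co3 (0.70), odf3l2a (5.93) and pigrl2.3 (3.06) in both. odf3l2a, at -0.08 in both pools, also reversed with library size only (0.23), limma voom (1.11), without control replicate 1 (0.95, and -0.66 without control replicate 3, the range with a control left out) and with TPM (1.65, or 1.93 with a pseudocount of 0.1). pigrl2.3, at -1.37, reversed with TPM (0.67, or 0.79). The cause was not tested.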

Other observations

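All tests in this part were chosen after the results they bear on were seen. Control replicates 1 and 2, made with the same library volume, differed in markers of the extra-embryonic layers. Of 13 enveloping layer markers, 12 were higher in control replicate 2 than in control replicate 1, with a median log2 difference of 2.99. The keratin genes krt4 (45.1 and 372 CPM in control replicates 1 and 2), krt8 (24.8 and 204 CPM) and krt92 (1.45 and 91.7 CPM) and the claudin gene cldne (126 and 561 CPM) were among them, while klf17 was at 599 and 507 CPM. Of 8 yolk syncytial layer markers, 7 were higher, with a median of 1.56, including hnf4a (3.74 and 31.9 CPM) and afp4 (0.936 and 36 CPM). Zygotic genes had a median difference of 0.68, with 33 of 40 higher, the p53 list one of 0.79, with 16 of 17 higher, and the interferon list one of 0.99, with 8 of 11 higher and isg15 at 347 and 1410 CPM. These are single libraries, so the differences have no replicate check. Control replicate 3 and both pools lay between them for krt4 (320, 199 and 236 CPM) and krt8 (106, 51.5 and 67.5 CPM). Other markers did not follow this, such as ppl (8.85 and 15.2 CPM in control replicates 1 and 2, then 21.8, 32.8 and 27.4 CPM) and krt5, at 0.681 and 26.7 CPM and at 42.2 CPM in control replicate 3.

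Transcripts with low counts in the pool of 25 alone included pabpn1l, at 74.3 CPM against 285 to 853 CPM in the other 4 libraries, the apoptosis inhibitor gene birc5a (24.8 CPM against 49.6 to 220 CPM) and the dynein light chain gene dynlrb1 (40.9 CPM against 83.6 to 279 CPM). By the 2-fold rule, 31 genes lay below and 25 above all 4 other libraries in the pool of 25, and 19 and 30 in the pool of 10. The same counts were 90 and 104 for control replicate 1, 74 and 257 for control replicate 2, and 105 and 89 for control replicate 3.

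Control replicate 3 lay with both pools and apart from control replicates 1 and 2. Sequencing depth alone would not give this, since 701 of the 748 genes lower in control replicates 1 and 2 were also lower after all libraries were thinned to the smallest total (798 in all). Transcript length may account for part of it, as 83.7% of the 748 genes were lost with a length correction. Spearman's rho of each library's deviations with length was -0.688 and -0.616 in control replicates 1 and 2. It was 0.545 in control replicate 3 and 0.556 and 0.627 in the pools of 10 and 25. Each gene's deviations were from its mean over the 5 libraries and sum to 0. A downward trend in control replicates 1 and 2 thus forces an upward one in the sum of the others, so the positive values are no separate evidence. After the correction 233 genes were lower, against at most 26 in any other pair of libraries, and the 233 include genes outside the 748. The length was estimated from the deposited tables, so an incomplete correction is possible, and whether length is the whole cause stays open. The pair made at the larger library volume was the 1 of the 10 pairs with as many lower genes (the next had 37), so library volume stays open and cannot be told apart from anything else these 2 libraries share, such as a shared day or clutch. No biological explanation was tested, as the labels put all 3 controls in one group.

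The 37 genes lower in both pools are more than the 10 guides of the smaller pool, so they cannot all be direct targets of their own guides. Simulated unchanged pools with shared controls had a mean of 41.7 lower genes in common. Their lists held 350 and 359 lower genes, where 93 and 130 were observed. These simulations therefore neither show nor exclude that the number comes from chance values of the shared controls. The 73 genes higher in both pools were above the highest of the simulations (50), though the simulated controls held no library volume difference. Transcript length could account for part, as 59.5% of the 37 genes were lost with the length correction. The corrected values still gave 26 lower genes, 15 of them among the 37, so the number fell by less than the loss of members. Of the 73 higher genes, 25 were among the 44 found with the correction. The 10 splits into pairs are too few for a share under 0.05: the real pair gave 37 and the highest other 748, which follows the library volume, and 2 of the 10 splits gave at least 37. An effect of the guides on some of these genes stays open as a hypothesis, to be tested with replicate libraries of each pool and of controls, all made at the same volume.

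abhd17c was lower in both pools by about as much as szrd1, a difference in log2 fold change of -0.058 with the volume term. Library volume stays open: control replicate 3, made at the volume of the pools, was 6.18-fold above the higher pool, but the gene was chosen for lying below this single library too. A trend with transcript length is argued against, since the lowest control stayed 6.06-fold above the higher pool after the length correction (3.82-fold before). A candidate explanation is that both pools held a guide against abhd17c, or that the szrd1 guide acted on it, and these cannot be told apart here because the labels name 1 guide target. This is a hypothesis from data in which the gene was found. Embryos injected with the szrd1 guide alone would test whether a separate guide is needed for the lower abhd17c level. They would not tell an action of the szrd1 guide on abhd17c from an effect of the loss of szrd1.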
